A study of Mus musculus with 4 samples.

How the data were processed

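Lung metastases of the 4T1 mouse mammary tumour line in BALB/c mice were studied by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against DNMT3B, a de novo DNA methyltransferase. The series holds 4 libraries. 2 are DNMT3B ChIP libraries and 2 are input libraries, and both kinds carry the lung labels 3 and 5. Nothing in the labels says whether these come from separate mice.

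The values used here are base positions and distances, deposited as 2 lists of regions for the whole series. Per the submitters' processing notes, reads were aligned with Bowtie2 (version given as 2.10), and regions were called with MACS (version given as 1.4) and SICER. The deposited MACS list is itself named for MACS2, and its name counts 4304 peaks, which is its number of lines. Neither difference could be settled from the files. Per the file headers, neither list carries a read count, a fold enrichment, a score or a p-value for a region. Whether the authors pooled the libraries before calling is not given in the sources used here. The depth of each library is therefore unknown, no value belongs to a library, and no spread between replicates could be computed.

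The MACS list, which MACS makes for narrow enrichment, gave for each line a region, its nearest gene, the distance to it and the wording of the overlap. It held 4304 lines but 1705 distinct regions, and lines of the same region were identical in gene, distance and wording. Each distinct region was counted once. Positions carried at most 6 significant digits, so starts of 7 digits fell on multiples of 10 bp (270 regions), those of 8 digits on multiples of 100 bp (989 regions) and those of 9 digits on multiples of 1000 bp (446 regions). As a result 529 regions had equal start and end. An end written as a question mark, on 2 lines, was set to the start. Region widths are thus known only to these steps, and so are distances to genes that follow from these positions.

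The SICER list, which SICER makes for broad enrichment, held 8242 islands, with starts and widths in steps of 200 bp. Each was paired with a single gene and with that gene's transcript positions. The overlap length in all 8242 lines equalled the overlap with the gene extended by 10 kb on each side, so islands farther from genes do not enter. What selection the name of the list refers to is not given in the sources used here. Spreadsheet dates had replaced 7 gene names, on 23 islands.

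The submitters' processing notes name mm10 as the genome build. Gene positions in the SICER list were compared with the RefSeq gene table of GRCm38, the same assembly, as a check of that label. Of 4067 genes compared, 322 (7.92%) had an end within 1 kb of GRCm38, and the median difference was 174.5 kb. Both lists share a set of gene positions: of 138 MACS regions outside a gene that the SICER list also names, 124 (89.9%) implied the same gene end within 10 bp. The build of the printed positions is therefore not known, and positions are given as deposited. No positions were converted. No position from the RefSeq table is printed. Beyond names, gene lengths and biotypes, its positions were used only for this check, for splitting regions by whether both sets of positions are equal, and for the tests of the build in the closing section. Genes were matched by transcript accession, symbol or unique synonym, for 99.5% of MACS regions and 99.9% of SICER islands.

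Placement tests compared the observed share of regions with 1000 random placements of the same widths on the same chromosomes, within the span of positions seen in both lists. The test of MACS regions against SICER islands was one-sided and required 1 shared bp, and those of midpoints at promoters and in gene bodies were two-sided. Assembly gaps were not excluded. Gene starts and bodies were those of 3799 protein-coding transcripts that the SICER list gives. These all lie near an island, so the tests at gene starts and in gene bodies cover that part of the genome only. MACS regions lay in islands more often than random placements did, so this choice of genes can raise their excess over random placement. A promoter was 1 kb either side of a gene start. Counts per chromosome were compared with each chromosome's share of the span by exact two-sided binomial tests, with Benjamini-Hochberg adjustment over 20 chromosomes. The span stands in for the sequenced length that was planned.

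A gene was assigned a MACS region that overlapped it or lay up to 5 kb upstream by the deposited distance. It was assigned a SICER island whose midpoint lay in its body or up to 5 kb upstream. For 18 gene lists, members with a region were compared with the other protein-coding genes, 21631 in all, by Fisher's exact test (two-sided), adjusted over the lists. This was the planned fallback where no annotation of the build is given. Exact 95% binomial intervals cover counting error only. The overlap between the genes of both lists was tested in the same way and was not planned. Named genes were the 5 protein-coding genes with most MACS regions, up to 4 members per list with a MACS region, those in an island first and then in alphabetical order, and Dnmt3b. Parts of the rule that rank by fold enrichment, score or ChIP over input ratio could not be applied. Gene lists, naming rules and planned tests were fixed before the data were examined. The span as expectation and the restriction to genes of the SICER list were settled afterwards, as was the ratio given for chromosome 16 alone.

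GC content, repeats, GC-matched placement and ChIP over input ratios were not analysed here, since they need a genome sequence or read counts. Alternatives tried were a stricter overlap, wider promoter windows, all annotated genes, islands in place of regions, and other distances from genes. Those added after seeing the data were moves of 50 to 300 kb, every line counted, regions widened by the rounding error, regions split by position equality, chromosome 16 left out, other ways of counting chromosomes, random genes of the same 20 length bins (10000 draws, lengths from GRCm38), and the genes of chromosome 18 as background for the clustered protocadherins.

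The tests were tried on simulated data. With 1705 regions placed at random, 6 of 100 simulations passed p of 0.05 in the placement test, and all 100 did with 10% of regions set into islands. Over 21631 genes with hits drawn regardless of gene length, 5 of 1800 list tests passed by Fisher's exact test and 3 of 1800 with matched lengths. The Wnt list of 47 members, planted at about 4 times the background, was called in 81 of 100 simulations. No other list was planted, so this share does not describe the smaller lists. With expected shares, 5 of 2000 chromosome tests passed, and a chromosome set to 2 times its share passed in all 100. Simulated regions were drawn independently of each other, so the placement and chromosome simulations do not describe false calls where regions cluster. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.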

Results

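DNMT3B, an enzyme that places new methyl groups on cytosines, was mapped by ChIP-seq in lung metastases of 4T1 cells, a BALB/c mouse mammary tumour line that spreads to the lung. The series comprised 2 DNMT3B ChIP libraries and 2 input libraries of sheared chromatin without immunoprecipitation, each kind with the lung labels 3 and 5. The data were a MACS list of narrow regions and a SICER list of broad islands, both given as positions with gene names. No read counts accompany the positions, so the depth of each library is unknown, and p-values describe where regions lie, not how far libraries differ. The comparisons addressed where in the genome the antibody enriched DNA and at which genes.

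The MACS list held 1705 distinct regions, and the SICER list held 8242 islands covering 50.04 Mb. Islands had a median width of 4800 bp, with quartiles of 3000 and 7600 bp and a maximum of 169800 bp. Among the MACS regions with the finest positions, the median width was 155 bp, with quartiles of 80 and 250 bp. MACS regions were assigned to 1295 protein-coding genes and SICER islands to 2900. At least 2 MACS regions were assigned to 225 of these genes, and at least 2 islands to 1100.

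MACS regions lay inside SICER islands far more often than randomly placed regions did. Of the 1705 regions, 521 (30.6%) shared at least 1 bp with an island, against 3.48% ± 0.451 (SD over 1000 placements) on the same chromosomes. This was an 8.79-fold excess (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The listed islands all reach to within 10 kb of a gene, and only 72 MACS regions (4.22%) lay over 10 kb from one. Part of the excess over random placement can therefore follow from how the island list was made. When each region was instead moved by 50 to 300 kb, which keeps its surroundings, 15.2% overlapped an island and the excess was 2.02-fold. In the other direction, 397 islands (4.82%) held a MACS region. Islands with a region had a median width of 7400 bp, against 4600 bp for the others. Socs1, an inhibitor of cytokine receptor signalling, lay under both calls: MACS regions on chromosome 16 from 10784400 to 10785000 and from 10785700 to 10786200 fell in an island from 10780200 to 10789199.

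MACS regions gathered at gene starts. Of the 1705 midpoints, 518 (30.4%) lay within 1 kb of the start of a protein-coding gene with a known position, against 0.446% ± 0.165 (SD) for random placements, and 1.75% after moves of 50 to 300 kb. Both excesses, 68.1-fold and 17.4-fold, had p = 0.002 in two-sided permutation tests, the smallest possible. In 1 kb bins around gene starts, the first kilobase of the gene held 355 midpoints and the kilobase before it 180. Together these exceed the 518 midpoints, so the bin counts are not a split of distinct midpoints. Rounding of positions, to 1000 bp for some regions, also blurs the division between the bins. Bins beyond 2 kb upstream and 3 kb downstream held 13.0 on average and 21 at most. Of SICER midpoints, 6.94% lay within 1 kb of a gene start. The gene starts are those of genes paired with islands, so an excess of islands over random placement there follows from how the list was made. MACS regions also lay in islands more often than random placements did. Part of their excess over random placement at these gene starts can therefore follow from the choice of genes.

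**Figure D1:**
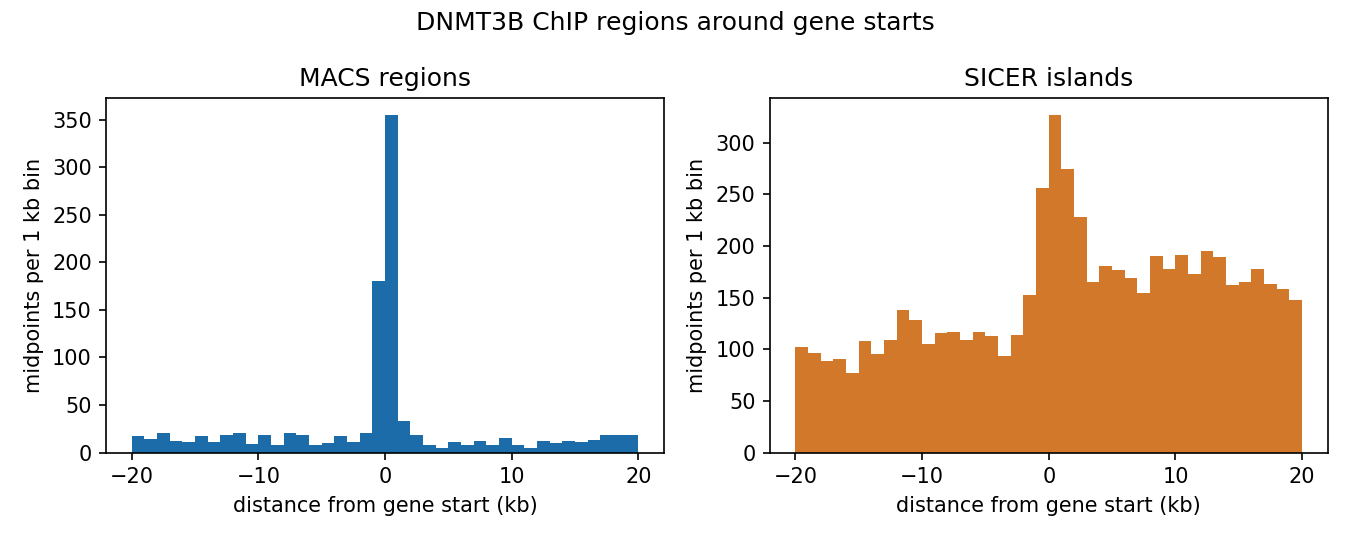
Number of midpoints of MACS regions (left) and SICER islands (right) per 1 kb bin against the distance in kb from the start of protein-coding genes, with the gene to the right of 0. The MACS bins reach 355 just inside the gene and 180 just before it, and the highest SICER bin holds 327 midpoints. Bin counts are not a split of distinct midpoints.

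The bodies of protein-coding genes paired with islands held 522 of the 1705 MACS midpoints (30.6%). Random placements gave 10.1% ± 0.735 (SD), a 3.04-fold excess (two-sided permutation p = 0.002, the smallest possible). Part of this excess can follow from the choice of genes, as at gene starts. Against moved regions, at 25.2%, the excess was 1.21-fold. By the deposited wording, which is not limited to genes paired with islands, 1294 MACS regions (75.9%) overlapped a gene. Of SICER islands, 72.0% overlapped the body of their paired gene. Of island midpoints, 67.4% lay in these gene bodies, a share not comparable with that of MACS regions because the genes were those paired with islands. Of the 1294 regions, 659 were described as contained within a gene, 421 only as in an intron and 213 overlapped a gene in part. A further 275 regions (16.1%) lay up to 1 kb upstream of a gene, and 4 up to 1 kb downstream.

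Chromosomes 16, 19, 11, 17 and 8 carried more MACS regions than their length predicts, and chromosome X carried almost none. Chromosome 16 held 334 regions where 64.7 were expected from its span, a ratio of 5.17 (exact 95% interval 4.67 to 5.68, adjusted p = 2.42e-132, exact binomial test). The ratios were 3.24 for chromosome 19, 2.77 for chromosome 11, 2.02 for chromosome 17 and 1.77 for chromosome 8. The X held 3 regions where 100.1 were expected, a ratio of 0.0300 (0.00618 to 0.0874, adjusted p = 3.59e-39, exact binomial test). In all, 5 chromosomes lay above their expected count and 12 below it at an adjusted p under 0.05. SICER islands lay above expectation on 7 chromosomes and below it on 12. The 5 chromosomes with a MACS excess and the 12 with a deficit departed in the same direction in both lists when the span gave the expectation. With the expectation from protein-coding genes, SICER islands turned to an excess on chromosomes 1 (ratio 1.15) and 12 (1.23), MACS deficits on 3, 10 and 12 no longer passed, and the MACS ratio of chromosome 11 was 1.77. On chromosome 16 the SICER ratio was 1.27 (1.15 to 1.401, adjusted p = 2.92e-06, exact binomial test), and on the X it was 0.0103. Gene starts within chromosomes 19 and 8 were compared for protein-coding genes paired with islands. Where gene positions in the lists equal GRCm38, 44.3% and 41.2% of these starts carried a MACS region. Where positions differ, 6.84% and 7.98% did. 4T1 is an aneuploid line, and copy number was not measured. On chromosome 16 the median difference of gene positions from GRCm38 was -0.092 kb. Whether the MACS excess there stems from the build in which part of the list stands, a candidate taken up in the closing section, was not settled.

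**Figure D2:**
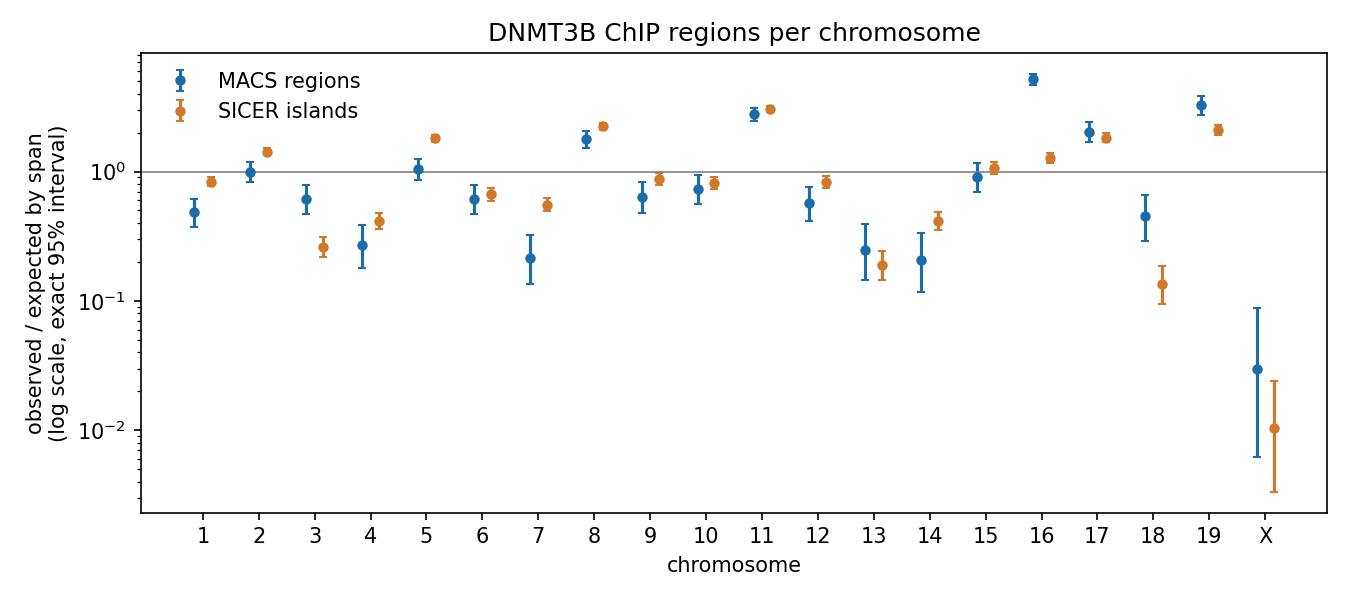
Observed over expected number of MACS regions and SICER islands per chromosome on a log scale, with the expectation from each chromosome's span of positions and exact 95% binomial intervals as bars. Chromosome 16 stands at 5.17 for MACS regions and 1.27 for SICER islands, and the X lies at 0.0300 and 0.0103.

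Genes of IL6 and STAT3 signalling and of Wnt signalling carried MACS regions more often than other protein-coding genes. Of all protein-coding genes, 5.99% did. In the IL6 and STAT3 list, 6 of 26 members had a region (23.1%, exact 95% interval 8.97 to 43.6, odds ratio 4.73, adjusted p = 0.0335, Fisher's exact test). Socs3, a feedback inhibitor of STAT3, had a region at 117831000 on chromosome 11, 319 bp upstream by the deposited distance. That position is rounded to 1000 bp, so the side of the gene start on which the region lies is uncertain. Stat5a had an intronic region at 100722000 on chromosome 11. Both lay in islands, and the region in an intron of the receptor gene Lifr, on chromosome 15 from 7079880 to 7079990, did not. In the Wnt list, 9 of 47 members had a region (19.1%, 9.15 to 33.3, odds ratio 3.74, adjusted p = 0.0299, Fisher's exact test). The receptor genes Fzd1 and Fzd5 and the ligand gene Wnt7a had regions in islands, with that of Wnt7a from 91361300 to 91361500 on chromosome 6 across the gene start. The region in Dvl1, on chromosome 4 at 155222000, lay outside islands. In permutation tests against random genes of the same length, neither list passed (adjusted p = 0.112 for IL6 and STAT3 and 0.104 for Wnt). Their members with a region were 3.39 and 2.84 times the mean of those draws. Genes were assigned by the deposited distance and wording. If part of the MACS list stands in other positions, a candidate taken up in the closing section, some assignments could be wrong. No gene list was tested for MACS regions by position equality or within chromosomes.

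The other 16 lists did not pass the adjusted test for MACS regions. Epithelial-mesenchymal transition genes came closest, with 6 of 32 members (18.8%, adjusted p = 0.0646, Fisher's exact test). This list passed with regions within 20 kb of the gene (7 of 32, adjusted p = 0.0169) and without chromosome 16 (6 of 30, adjusted p = 0.0306), by the same exact test. Ovol1, a transcription factor of epithelial cells, had 3 regions, among them 5560410 to 5560580 on chromosome 19 at the gene start. Grhl2 and the tight junction gene Cldn3 had 1 region each in an island, and Cldn7 had 1 outside. In NF-kB signalling, 5 of 29 members had a region (17.2%, adjusted p = 0.123, exact test). Rela, an NF-kB subunit, had a region 160 bp upstream that lay in an island, while those of Birc2, Birc3 and Nfkbiz did not. In PI3K and Akt signalling, 4 of 31 members had a region (12.9%, adjusted p = 0.287, exact test). Irs1, an adaptor of the insulin receptor, had 4 regions in an island of 6600 bp, the first from 82287200 to 82287600 on chromosome 1. Irs2 had 2 regions in islands, and Gsk3b and Rptor had 1 each outside islands.

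In the DNA methylation machinery, 3 of 21 members had a MACS region (14.3%, adjusted p = 0.287, exact test). The regions of Mbd3, a subunit of the NuRD complex, and of Gadd45b lay in islands, and those of Uhrf2 did not. No MACS region and no SICER island was assigned to Dnmt3b. In Notch signalling, 3 of 33 members had a region (9.09%, adjusted p = 0.618, exact test), with 3 in Notch1 and 1 in Hes1, all in islands, and 1 in Hey1, outside. TGF-beta and BMP signalling had 3 of 31 (9.68%, adjusted p = 0.618, exact test), with Skil, Smad4 and Smad7, all outside islands. Tumour suppressors had 5 of 38 (13.2%, adjusted p = 0.224, exact test), and the regions of Cdkn1b, Klf6, Nf1 and Rassf5 lay outside islands. Developmental transcription factors had 5 of 58 (8.62%, adjusted p = 0.618, exact test), with Hoxa9, Hoxa10, Hoxb9 and Hoxd13 among them, outside islands. Gnas was the member with a region among 30 imprinted genes (3.33%), Flt1 among 18 endothelial and stromal markers (5.56%) and Tfrc among 24 housekeeping genes (4.17%), each with adjusted p = 1 (exact test). No member had a region among 13 genes of prostaglandin E2 synthesis and receptors (adjusted p = 1, exact test), 34 germline genes (0.532), 57 clustered protocadherins (0.177), 22 lung epithelium markers (0.822) or 24 immune cell markers (0.618).

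SICER islands were more frequent at genes of several signalling lists. None lay at the clustered protocadherins, adhesion genes of a tandem array on chromosome 18. Of all protein-coding genes, 13.4% had an island. Of 18 lists, 10 lay above this share and 1 below at an adjusted p under 0.05 in Fisher's exact test. Notch signalling stood highest, with 15 of 33 members (45.5%, exact 95% interval 28.1 to 63.6, odds ratio 5.41, adjusted p = 0.000134, Fisher's exact test). Endothelial and stromal markers had 8 of 18 (44.4%, adjusted p = 0.00290), IL6 and STAT3 signalling 11 of 26 (42.3%, adjusted p = 0.000984), NF-kB signalling 12 of 29 (41.4%, adjusted p = 0.000838) and epithelial-mesenchymal transition 13 of 32 (40.6%, adjusted p = 0.000758), all by Fisher's exact test. PI3K and Akt signalling had 12 of 31 (38.7%, adjusted p = 0.00117) and Wnt signalling 17 of 47 (36.2%, adjusted p = 0.000627), by the same exact test. None of the 57 protocadherins had an island (adjusted p = 0.00150, Fisher's exact test). These neighbours are not independent, and 15 of the 454 other genes of chromosome 18 had an island (3.30%), which gives 1.88 expected members (p = 0.394, Fisher's exact test within the chromosome). These 8 lists also passed against random genes of the same length, with adjusted p between 0.00180 and 0.0270. Neither the exact test nor these draws hold the chromosome fixed, although islands were uneven across chromosomes. Only the protocadherins were compared within their chromosome. How far the excess of the other lists follows from the chromosomes of their members was not tested.

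A further 3 lists passed Fisher's exact test but not the permutation test with genes of the same length. By the exact test and then the permutation test, they were prostaglandin E2 synthesis and receptors with 5 of 13 members (38.5%, adjusted p = 0.0437, and 0.138 with matched length), TGF-beta and BMP signalling with 9 of 31 (29.0%, adjusted p = 0.0476, and 0.262) and tumour suppressors with 10 of 38 (26.3%, adjusted p = 0.0476, and 0.175). In this order, their members with an island were 2.52, 1.60 and 1.70 times the mean of the length-matched draws. Housekeeping genes had 4 of 24 members with an island (16.7%), the DNA methylation machinery 4 of 21, lung epithelium markers 3 of 22 (13.6%), imprinted genes 4 of 30 (13.3%), germline genes 4 of 34 (11.8%), developmental transcription factors 3 of 58 (5.17%) and immune cell markers 0 of 24. None of these passed, with adjusted p from 0.0977 to 1 in Fisher's exact test. Each island was paired with a single gene, so a neighbour of that gene counts as having none. With islands required within 2 kb of a gene start, 5 of the 18 lists passed in place of 11. Prostaglandin E2 synthesis and receptors was among the 5, with an odds ratio of 8.47 in place of 4.04 (adjusted p = 0.00559, Fisher's exact test). Of the 8 lists that passed with matched length, 4 then lost the call: NF-kB and Wnt signalling (odds ratios 2.82 and 2.37, adjusted p = 0.103 each), endothelial and stromal markers (odds ratio 1.69, adjusted p = 0.639) and clustered protocadherins (again 0 of 57 members, adjusted p = 0.0969), all by Fisher's exact test.

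**Figure D3:**
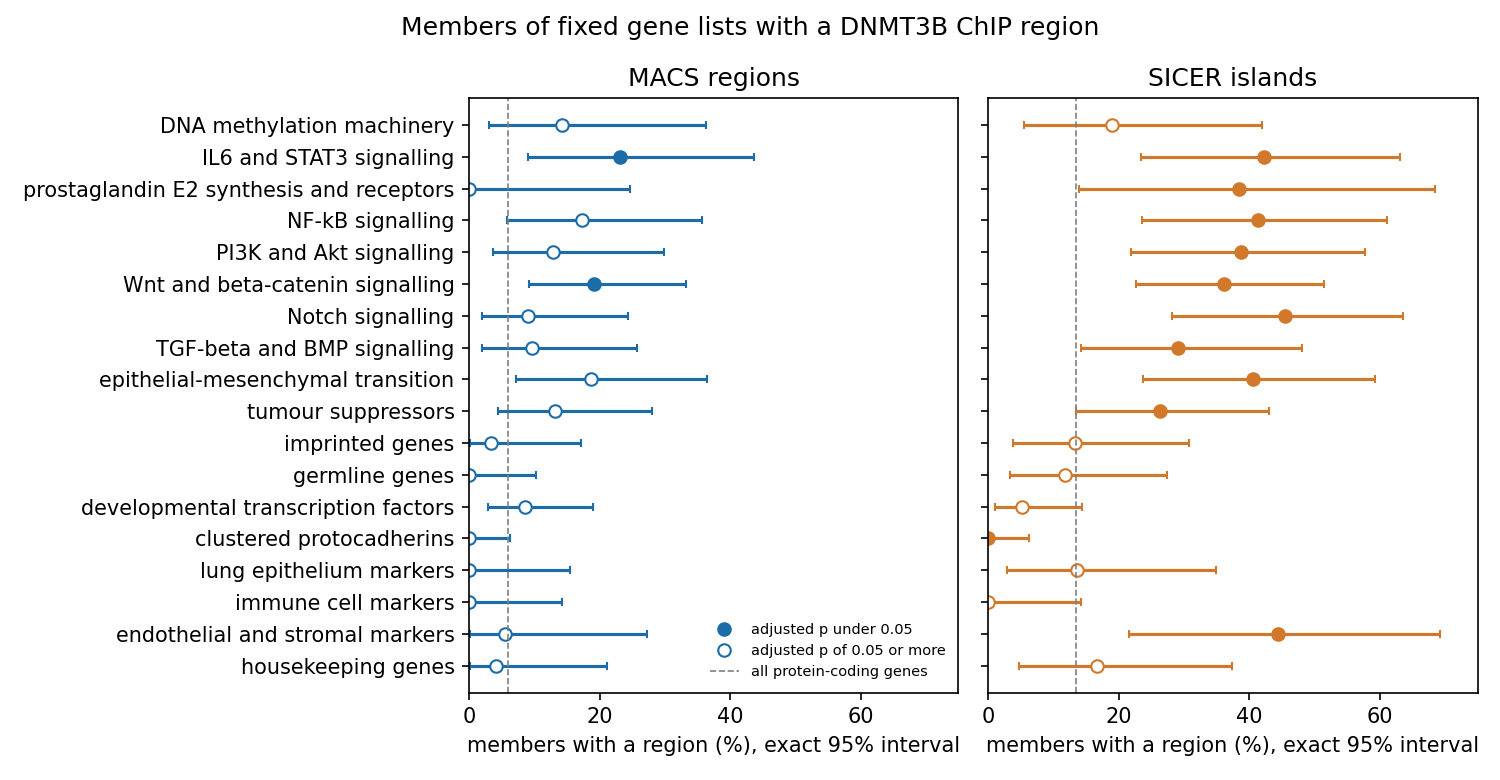
Percent of members of each gene list with a MACS region (left) and with a SICER island (right), with exact 95% binomial intervals as bars and the share of all protein-coding genes as a dashed line at 5.99% and 13.4%. Filled points have an adjusted p under 0.05, which holds for 2 lists on the left and 11 on the right.

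The genes with most MACS regions were Plec, Ptprs, Ing1, Ltbp3 and Scarf2. Plec, which encodes the cytoskeletal linker plectin, had 9 regions on chromosome 15 between 76002700 and 76014200, each contained within the gene by the deposited wording, and 8 of them lay in islands. Ptprs, a receptor tyrosine phosphatase gene on chromosome 17, had 8 regions, of which 5 lay in islands. Ing1, a chromatin reader gene on chromosome 8, had 6 regions from 462 bp upstream into the gene, of which 2 lay in islands. Ltbp3, whose product binds latent TGF-beta, had 6 regions on chromosome 19, and Scarf2, a scavenger receptor gene, had 5 on chromosome 16, all in islands.

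Both callers picked the same genes more often than independent lists would. Of the 1295 genes with a MACS region, 435 (33.6%) also had a SICER island, where 173.6 were expected from 2900 island genes among 21631 (odds ratio 3.67, p = 4.96e-83, Fisher's exact test). Random genes of the same length gave 196.7 ± 12.3 (SD over 10000 draws). This comparison was not planned. Which libraries entered each list is not given, so the overlap says nothing of repeatability between libraries.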

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

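Alternatives with moved regions, every line counted, widened regions, position splits, chromosome 16 left out, other chromosome counts, length-matched genes and the background of chromosome 18 were chosen after seeing the data. No paired analysis was possible because the lists hold no value per library, and for the same reason no library could be left out. Of 65 alternative values with a test, 53 kept their direction and side of the threshold, 11 kept their direction but no longer passed, and 1 reversed. Of 11 alternative counts, 9 lay within 1.5 times the main count, although some of these lost or gained calls, and 2 lay lower. SICER islands in place of MACS regions at promoters and in gene bodies are left out of these, since their outcome follows from how that list was made. The overlap of MACS regions with islands ran from 26.9% where gene positions differ from GRCm38 to 40.1% with every line counted, and each placement alternative of the MACS regions stayed above its random share. The share at promoters ran from 29.1% to 36.9% for MACS regions, and the chromosome 16 ratio of the MACS list from 4.76 with distinct nearest genes to 6.39 with every line counted.

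With random genes of the same length bins, 0 lists passed for MACS regions in place of 2, while 3 lists above and 1 below (clustered protocadherins) had an unadjusted p under 0.05. Epithelial-mesenchymal transition genes passed for MACS regions within 20 kb of the gene and without chromosome 16 (adjusted p = 0.0169 and 0.0306, Fisher's exact test). With islands required within 2 kb of a gene start, 5 lists passed in place of 11. TGF-beta and BMP signalling reversed, to an odds ratio of 0.450 from 1 of 31 members (adjusted p = 0.893, Fisher's exact test). That value cannot be told apart from the background. Fewer genes carry an island under that rule, and the cause was not tested otherwise.

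Not run, for want of scores, summits, read counts or a sequence, were stricter thresholds, islands selected by ratio, summits in place of midpoints, GC-matched placement, expectations from bases outside gaps and repeats, and the window around gene starts for MACS gene lists. Positions rounded to 1000 bp on the far parts of chromosomes limit what an overlap of narrow regions can show there.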

Other observations

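These observations and the tests of the share at GRCm38 gene ends and of copy number were chosen after the values were seen. The widest SICER islands gathered on chromosome 15, which carried 4.09% of all islands but 10 of the 20 widest. The widest spanned 169800 bp at Ndufb9, a gene of respiratory complex I, from 58755400 to 58925199. An island of 87600 bp lay at Pvt1, the long noncoding RNA gene beside Myc, from 61918400 to 62005999, and islands of 84800 bp and 77000 bp lay at Gga1 and St3gal1. The median width on chromosome 15 was 5200 bp, against 4800 bp elsewhere. Among single genes, Mad1l1, a spindle checkpoint gene, carried 25 islands, Agap1 24 and Rbfox3 21. These are long genes, of 312.9, 440.5 and 421.8 kb in GRCm38, against a median of 17.3 kb for protein-coding genes. No explanation was tested for these values.

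MACS regions crowded where gene positions in the lists equal those of GRCm38: 30.7% of regions lay there, and 8.53% of SICER islands, and no biological explanation other than copy number was tested. Copy number of whole chromosomes predicts equal shares in both kinds of segment, and chromosomes 8 and 19 hold both kinds. Among protein-coding genes paired with islands, gene starts there carried a region more often where positions are equal (odds ratio 9.31, 95% interval 5.42 to 15.98, 564 genes). The interval treats genes as independent, although neighbouring genes share a segment, so it can be too narrow. The direction was the same on both chromosomes, which argues against whole-chromosome copy number there. Copy number stays open on chromosome 16, where the median difference from GRCm38 was -0.092 kb and this comparison was not available. A candidate explanation is that part of the MACS list stands in GRCm38 positions, since where positions differ 18.5% of regions lay within 1 kb of a GRCm38 gene end, against a 95% range of 6.48% to 9.38% for moved regions. A separate candidate, that some regions were listed in both sets of positions and so are duplicates among the distinct regions, was tested as fixed beforehand: 24 regions had another at the local offset (range 5 to 17 for other distances). A further test of the first candidate, also fixed beforehand, missed its prediction. Regions far from genes lay at GRCm38 gene ends no more often than regions overlapping genes (odds ratio 0.681, 0.330 to 1.403). The rule fixed beforehand counted this outcome against the candidate. The interval also holds values above 1, and reading it as leaving the question open was settled after the value was seen.

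Lines per distinct MACS region ranged from 1 to 55, and 49.4% of regions stood on more than 1 line. The idea that each line stands for a transcript of the gene predicted a Spearman correlation of at least 0.5 with the number of RefSeq transcripts of the nearest gene. Across 1697 regions, which are not independent replicates, rho was -0.0540 (95% bootstrap interval -0.0998 to -0.00888), which argues against it. What sets the number of lines remains open.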
